A study of Loxodonta africana with 12 samples.

How the data were processed

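RNA was sequenced from African elephant (Loxodonta africana) blood cells in 12 libraries. Per the labels' protocols, total RNA was column-purified and made into libraries with a stranded Illumina kit after depletion of ribosomal RNA. The labels put 3 libraries in each of 4 groups, namely untreated and irradiated (2 Gy) at 5 h and at 24 h, and number the replicates 1 to 3. They do not say whether replicates came from separate animals, blood draws or cultures, so the p-values measure the spread between these libraries, which may be technical. How cells were isolated and cultured is not given in the sources used here.

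The authors deposited 1 table per time point, each holding both groups and the same 16406 Ensembl genes, of which 15608 are marked protein coding and 2663 carry no symbol. Per the file headers, the tables hold raw read counts per gene and library, which were whole numbers here and were the input of every test. The authors also deposited FPKM values, whose per-library constant was used only to recover the read total behind them. That total exceeded the sum of the counts by 0.006% to 0.082%, so a small part of the reads behind the FPKM values lies outside the rows. What share of all sequenced reads entered that total is not known here. The authors' deposited log2 ratio of the groups was read only to compare it with the fits, and it is coded as untreated over irradiated, opposite to the direction used here. For MDM2 the authors' deposited table gives -2.62 at 5 h. The 12 columns of regularized log values and the authors' adjusted scores and splicing columns were not used here. Per the file headers, gene coordinates are in scaffolds of an African elephant assembly. The header does not state whether they count from 0 or 1, and they are printed as given. The aligner, the counting program and whether counting used strand are not given in the sources used here, so overlapping genes on opposite strands cannot be separated. No reference genome was used. Of the gene models marked protein coding, 86.4% have an exon length that is a multiple of 3.

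Library totals ranged from 31.1e6 to 38.1e6 counts at 5 h and from 18.0e6 to 37.4e6 at 24 h. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Each irradiation comparison used the 6 libraries of its time point without a block. The difference of the irradiation effect between the times was an interaction term over all 12 libraries. Untreated libraries at 24 h were compared with those at 5 h in a fit of those 6. Standard errors of log2 fold changes were taken from the F statistic. CPM values are means ± SD of n = 3 libraries, scaled within the fit they are quoted for.

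Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated per list. With an estimated correlation camera rests on the residual degrees of freedom of the fit. These are few with 6 libraries and fewer still with the replicate block. A list can then lose its call even where its estimated correlation is low, so a lost call is weak evidence against a change. fry gave tests for change in any direction and for change in a shared direction. The 22 lists cover p53 targets, DNA repair, mitosis, DNA replication, apoptosis, interferon-stimulated, NF-kB and inflammatory, immediate early and stress, NRF2, unfolded protein response and ATF4, glycolysis and hypoxia, and ribosomal protein genes, mitochondrially encoded genes, lymphocyte activation, and markers of T cells, B cells, NK and cytotoxic cells, monocytes and macrophages, neutrophils, platelets, erythroid cells, and stromal and endothelial cells. No gene is in more than 1 list. At least 5 tested members were required, which left 21 lists. The mitochondrially encoded list matched 0 rows and was not analysed here. Genes shared by the calls at both times were counted per direction and tested with Fisher's exact test over genes, which are not independent replicates.

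Genes were named by a rule. Like the lists, the tests and most of the repeats named below, it was fixed before the data were examined. Per time point it takes the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 CPM and no overlap between the groups. It adds up to 4 members of each list with the smallest p, and always CDKN1A, MDM2, BAX, BBC3, LIF and ATM. For the comparisons between times it takes 5 per direction, and the requirement of no overlap was not applied to the interaction, which has no such pair of groups. BBC3 and LIF were not analysed here. A part of the genes so selected is described, and some are not reported here.

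Whether replicate numbers pair the libraries was checked by correlating deviations from the group means over 9762 genes. At 5 h, untreated and irradiated libraries of the same number correlated at 0.66, 0.67 and 0.81, so the numbers of the labels pair them. A fit with the replicate block is therefore given beside 5 h results where it changes a call. Pairs of libraries within a group differed by a chi-square of 17.4 to 88.8 per degree of freedom, so none was the same library sequenced again. This does not tell whether they came from separate samples.

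The tests were tried on simulated counts with 200 changed genes. These were picked only among genes above a minimum mean count, so the recovery does not cover weakly expressed genes. Each setting was drawn a single time, with the spread that edgeR had estimated without the block. At 5 h (12969 genes) edgeR recovered 87% of 2-fold and 100% of 4-fold changes with 5.56% false calls. At 24 h (14373 genes) it recovered 78% and 96% with 8.42% false calls. For the interaction (15200 genes) the figures were 53%, 95% and 3.9%. For untreated libraries over time (13445 genes) they were 91%, 100% and 8.61%. DESeq2 1.42.0 made 15.6% false calls in the 5 h simulation and 16.9% in that of 24 h. With a replicate effect added at 5 h, the fit with the replicate block recovered 93% of 2-fold changes with 11.1% false calls, against 68% and 1.18% without it. The tests were repeated with DESeq2, RLE scaling, no filter, a filter of 1 CPM in 3 libraries, an adjusted p below 0.01, a 2-fold minimum, the replicate block, all 12 libraries in 1 fit and leaving out each library in turn. DESeq2 with the block, the block with an estimated list correlation and thinning of the 24 h libraries to the lowest total were chosen after seeing the data.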

Results

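Blood cells of African elephants were profiled by RNA sequencing with and without irradiation at 2 Gy, 5 h and 24 h later, with 3 libraries in each of the 4 groups. The study asks which genes respond to DNA damage in their cells. At 5 h the untreated libraries held 31.1e6, 36.0e6 and 35.8e6 counts and the irradiated libraries 37.2e6, 31.1e6 and 38.1e6 counts. At 24 h the totals were 22.9e6, 30.8e6 and 37.4e6 in untreated and 23.8e6, 18.9e6 and 18.0e6 in irradiated libraries. The first principal component, which held 77.8% of the variance, separated the 2 times, and the second, with 9.24%, separated irradiated from untreated libraries within each time.

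The first comparison asked what irradiation changed by 5 h. Known targets of p53 rose. MDM2, a ubiquitin ligase (ENSLAFG00000005885, scaffold 2, 59036999 to 59064440, plus strand), rose from 163 ± 8.82 to 1018 ± 127 CPM (n = 3 per group, edgeR log2 fold change 2.64 ± 0.11, adjusted p = 2.4e-05). CDKN1A, the cell cycle inhibitor p21 (ENSLAFG00000009778, scaffold 0, 128580859 to 128583266, minus strand), rose from 188 ± 37.1 to 471 ± 13.2 CPM (log2 fold change 1.33 ± 0.14, adjusted p = 0.0028). BAX, which permeabilizes the mitochondrial outer membrane in apoptosis, rose from 20.7 ± 0.43 to 74.7 ± 0.96 CPM (log2 fold change 1.85 ± 0.06, adjusted p = 1.4e-05). Of 94 p53 targets tested, 21 rose and 1 fell, or 26 and 7 when adjusted over the list alone, and 38 higher and 8 lower with the replicate block. The list was higher than other genes (camera, median log2 fold change 0.16, adjusted p = 9.5e-10, and 0.018 with an estimated correlation). The estimated correlation of the list was 0.00029 without the block, below the preset 0.01. With the replicate block and an estimated correlation its adjusted p was 0.52. The block leaves few residual degrees of freedom for that test, so 0.52 does not show that the list is unchanged. Cyclin G1 (CCNG1) and RPS27L rose by 2.15 ± 0.08 and 2.06 ± 0.07 on the log2 scale.

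In all, 207 of 12969 genes passed at 5 h, 145 higher and 62 lower after irradiation. With the replicate block the count was 2655, 1369 higher and 1286 lower, including all 207 of the fit without it. The 8 largest rises were of PHLDA3, a repressor of AKT (ENSLAFG00000016242, scaffold 13, 5461272 to 5461650, minus strand, log2 fold change 5.94 ± 0.24, adjusted p = 2.4e-05), GNAT1 (5.42 ± 0.40), the focal adhesion protein TNS1 (4.03 ± 0.30), SASH1 (3.94 ± 0.34), the semaphorin receptor PLXNB2 (3.55 ± 0.17), SDK2 (3.36 ± 0.18), CCDC34 (3.32 ± 0.26) and IZUMO4 (3.11 ± 0.20). GNAT1 is the transducin subunit of rod photoreceptors and went from 0.071 ± 0.052 to 3.07 ± 0.68 CPM. The 8 largest falls were of the amino acid transporter SLC16A10 (-2.06 ± 0.21), SULF1 (-1.96 ± 0.28), MCOLN3 (-1.60 ± 0.23), FILIP1L (-1.44 ± 0.15), the somatostatin receptor SSTR3 (-1.42 ± 0.17), the linker histone HIST1H1D (-1.40 ± 0.25), FAM129C (-1.32 ± 0.13) and the receptor tyrosine kinase KIT (-1.30 ± 0.18). By the naming rule the groups do not overlap in these 16 genes, which also holds for 18.6% of all genes tested. HIST1H1D belongs to a family of near-identical genes, so its value is uncertain. Leaving out untreated replicate 1, 2 or 3 gave 115, 107 and 129 calls, and leaving out irradiated replicate 1 or 2 gave 86 and 97. SULF1 lost its call without untreated replicate 1 or 3 or irradiated replicate 1 or 2 (adjusted p 0.051 to 0.077). MCOLN3 lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 2 (adjusted p 0.052 to 0.074). HIST1H1D lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p 0.07 to 0.2). KIT lost its call without untreated replicate 1 or irradiated replicate 1 or 2 (adjusted p 0.062 to 0.087). With all 12 libraries in 1 fit the adjusted p was 0.33 for SULF1 and 0.054 for MCOLN3.

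Genes of mitosis were lower at 5 h. Of 66 tested, 2 fell and 2 rose, or 15 and 2 adjusted over the list alone, and the replicate block called 24 lower and 4 higher (median -0.33, camera adjusted p = 1.1e-09, adjusted p = 0.63 with an estimated correlation). The kinetochore protein CENPF fell (log2 fold change -0.996 ± 0.13), and the mitotic kinesin KIF18B went from 0.58 ± 0.073 to 0.19 ± 0.003 CPM (adjusted p = 0.043, 0.078 in DESeq2, 0.06 without a filter and 0.077 with all 12 libraries in 1 fit). SKA3 and NCAPG, also of the mitosis list, rose by 1.95 ± 0.28 and 0.82 ± 0.14. DNA replication genes were lower as a list (median -0.09, adjusted p = 0.019, 0.63 with an estimated correlation), with 1 of 57 called higher and 0 lower, against 5 higher and 12 lower with the replicate block. At an unadjusted p below 0.05 edgeR gave 3 higher and 14 lower, and DESeq2 called 2 and 0. The gene called without the block was DNA2, a nuclease and helicase of replication and end resection, which rose by 2.22 ± 0.10. DNA repair genes did not pass as a list (1 of 59 called higher, 0 lower, with the replicate block 4 higher and 7 lower, median -0.04, adjusted p = 0.63). For BRCA1 the log2 fold change was -0.70 ± 0.17 (adjusted p = 0.11, 0.00093 with the replicate block). The replication list lost its call without untreated replicate 3 (adjusted p = 0.12) or irradiated replicate 1 (0.057), and its median was -0.06 without untreated replicate 2. CENPF lost its call without irradiated replicate 1 or 2 (adjusted p 0.051 to 0.065). KIF18B lost its call without any 1 of the 6 libraries (adjusted p 0.11 to 0.21). SKA3 lost its call without untreated replicate 2 or irradiated replicate 1 or 2 (adjusted p 0.074 to 0.081). NCAPG lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p 0.065 to 0.12).

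The B cell and T cell marker lists were lower at 5 h by camera with its preset correlation, but not with an estimated one. All 17 B cell markers had a negative log2 fold change (median -0.44, camera adjusted p = 4.1e-08, 0.63 with an estimated correlation). FCRL1 fell by 0.68 ± 0.12 and was the only one called, and 10 fell when adjusted over the list alone. With the replicate block 13 were called, among them CD22 (-0.41 ± 0.09, adjusted p = 0.092, 1.2e-05 with the block). T cell markers were lower as a list (median -0.25, adjusted p = 0.0023, 0.75 with an estimated correlation), with 0 of 21 called by edgeR (2 lower at an unadjusted p below 0.05, 1 lower by DESeq2) and 11 lower with the replicate block. For CD27 the log2 fold change was -0.65 ± 0.17 (adjusted p = 0.13, 3.7e-05 with the block) and for IL7R -0.49 ± 0.24 (0.44, 2.1e-05 with the block). NK and cytotoxic markers passed with the replicate block (median -0.23, adjusted p = 0.073, 0.012 with the block), as did interferon-stimulated genes (median -0.08, 0.32 and 0.0018), with 8 and 13 genes called lower with the block. NK markers also passed with the stricter filter (adjusted p = 0.029). With the block and an estimated correlation, a test with few residual degrees of freedom, those adjusted p were 0.59 and 0.54. The T cell call was lost without untreated replicate 3 (median -0.17, adjusted p = 0.12) or irradiated replicate 1 (0.064). NK markers passed without untreated replicate 1 (adjusted p = 0.0079) or irradiated replicate 3 (0.041), and interferon genes without untreated replicate 2 (3.4e-05) or irradiated replicate 3 (0.0014). FCRL1 lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p 0.057 to 0.12). CD27 passed without irradiated replicate 3 (0.017).

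Immediate early and stress genes were higher at 5 h as a list (median 0.20, adjusted p = 0.027, 0.75 with an estimated correlation), with 1 of 29 called, GADD45G (log2 fold change 0.86 ± 0.14, adjusted p = 0.028). With the replicate block 16 were called, including the transcription factor EGR1 (0.33 ± 0.15, adjusted p = 0.42, 1.8e-05 with the block) and the chaperone DNAJB1 (0.29 ± 0.14, 0.43 and 0.00015). The list's call was lost without untreated replicate 2 (median 0.07, adjusted p = 0.39), irradiated replicate 1 (0.12, 0.19) or irradiated replicate 3 (0.12, 0.14). GADD45G lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p 0.065 to 0.14), and with all 12 libraries in 1 fit (0.66).

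The other lists did not pass at 5 h. Their medians were -0.08 (adjusted p = 0.15) for apoptosis genes, -0.04 (adjusted p = 0.67) for NF-kB and inflammatory genes, -0.04 (adjusted p = 0.68) for NRF2 genes, 0.02 (adjusted p = 0.77) for the unfolded protein response, -0.04 (adjusted p = 0.6) for glycolysis and hypoxia, -0.02 (adjusted p = 0.94) for ribosomal proteins and -0.08 (adjusted p = 0.67) for lymphocyte activation. Among markers they were 0.11 (adjusted p = 0.56) for monocytes and macrophages, 0.07 (adjusted p = 0.67) for neutrophils, 0.13 (adjusted p = 0.63) for platelets, -0.14 (adjusted p = 0.74) for erythroid cells and -0.04 (adjusted p = 0.51) for stromal and endothelial cells. Without untreated replicate 1 the apoptosis list (0.045) and the erythroid list (0.047) passed, both lower, and without untreated replicate 2 the stromal list (0.021), also lower. The replicate block called, higher and lower, 3 and 7 of the apoptosis genes, 5 and 9 of the NF-kB genes, 2 and 6 of the NRF2 genes, 4 and 5 of the unfolded protein response genes, 5 and 7 of the glycolysis genes, 3 and 1 of the ribosomal protein genes, 6 and 4 of the lymphocyte activation genes. For markers they were 8 and 5 of the monocyte markers, 3 and 3 of the neutrophil markers, 2 and 1 of the platelet markers, 1 and 0 of the erythroid markers, 0 and 3 of the stromal markers. Single members did change. BCL2L1, which encodes the survival protein BCL-XL, rose by 0.97 ± 0.09, the cytokine IL6 by 2.23 ± 0.40, the platelet glycoprotein GP9 by 2.496 ± 0.27 and the ribosomal protein RPS19 by 0.52 ± 0.08. IL6 lost its call without untreated replicate 1 or 2 or irradiated replicate 1, 2 or 3 (adjusted p 0.053 to 0.14). RPS19 lost its call without untreated replicate 1 or 2 or irradiated replicate 1, 2 or 3 (adjusted p 0.066 to 0.12). For the damage kinase ATM the log2 fold change was 0.07 ± 0.06 (adjusted p = 0.7).

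**Figure D1:**
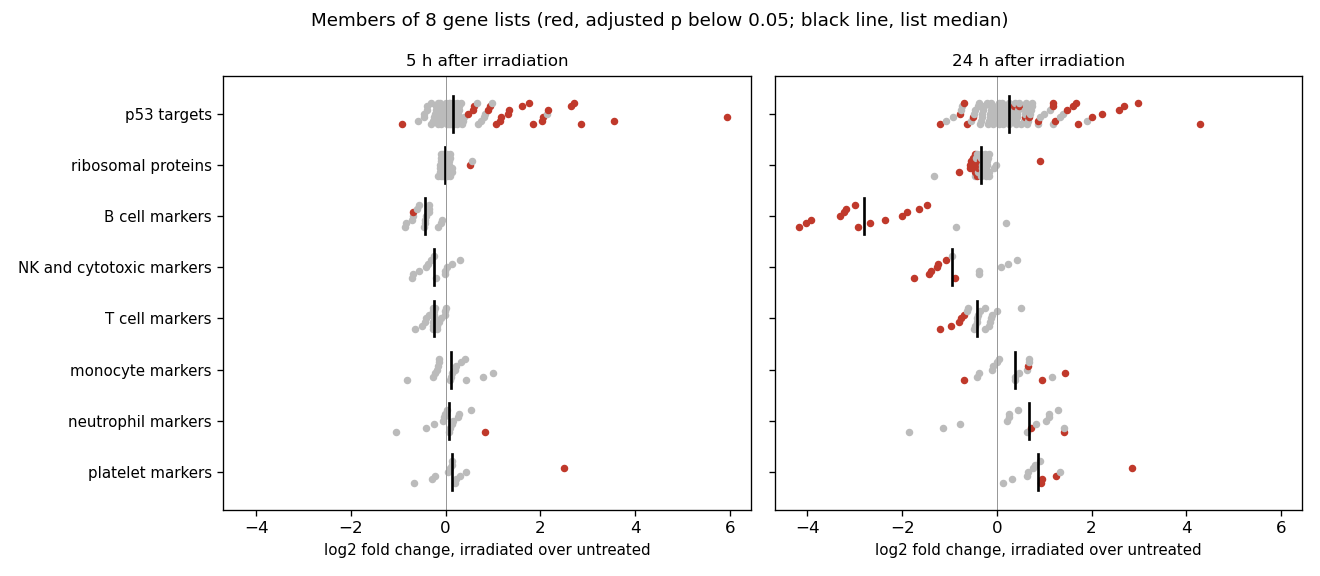
Log2 fold changes (x axis, irradiated over untreated) of the members of 8 gene lists at 5 h (left) and 24 h (right), 1 dot per gene, red where the adjusted p is below 0.05, with the list median as a black line. The median of the B cell markers lies at -0.44 at 5 h and at -2.80 at 24 h.

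The second comparison asked the same at 24 h. Of the 21 lists tested, the B cell markers had the lowest median. MS4A1, the B cell surface protein CD20 (ENSLAFG00000015517, scaffold 71, 9060073 to 9066418, minus strand), fell from 95.9 ± 10.2 to 5.84 ± 1.21 CPM (n = 3 per group, edgeR log2 fold change -4.04 ± 0.18, adjusted p = 0.00017). CD79B, a signalling chain of the B cell receptor (ENSLAFG00000014432, scaffold 31, 29707549 to 29710948, minus strand), fell from 92.9 ± 9.26 to 6.15 ± 1.36 CPM (log2 fold change -3.92 ± 0.18, adjusted p = 0.00017). The complement receptor CR2 fell from 54.5 ± 12.6 to 3 ± 0.61 CPM (log2 fold change -4.18 ± 0.24, adjusted p = 0.00032). Of 16 B cell markers tested, 14 fell and 0 rose, the same number as when adjusted over the list alone (median -2.80, camera adjusted p = 3.1e-17, 0.071 with an estimated correlation). The 2 not called, named after their values were seen, were FCER2 (-0.86 ± 0.66, adjusted p = 0.5), the low-affinity IgE receptor, and CD72 (0.20 ± 0.10, 0.32). None of the 21 lists held at 24 h with an estimated correlation. Estimated correlations ranged from -0.003 for lymphocyte activation to 0.72 for immediate early genes, with 0.087 for B cell markers and 0.023 for p53 targets. That test also rests on few residual degrees of freedom, so the lost calls do not measure correlation between genes alone.

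In all, 968 of 14373 genes passed at 24 h, 258 higher and 710 lower. The 8 largest falls also included the dendritic cell receptor CLEC9A (-4.30 ± 0.52), PLD4 (-3.93 ± 0.27), FAM129C (-3.74 ± 0.17), SYBU (-3.32 ± 0.31) and FCRL1 (-3.30 ± 0.15). CLEC9A had the largest fall of these 8, and no list of dendritic cell markers was tested. The 8 largest rises were of GNAT1 (4.87 ± 0.44), PHLDA3 (4.28 ± 0.29), the receptor NOTCH3 (3.85 ± 0.45), TNS1 (3.82 ± 0.25), the extracellular sulfatase SULF2 (3.05 ± 0.48), ZMAT3 (2.99 ± 0.18), IZUMO4 (2.87 ± 0.25) and GP9 (2.84 ± 0.42). Leaving out untreated replicate 1, 2 or 3 gave 416, 548 and 369 calls, and leaving out irradiated replicate 2 or 3 gave 293 and 462. SULF2 lost its call without irradiated replicate 2 (adjusted p = 0.064).

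Targets of p53 were higher at 24 h, with 18 of 99 called higher and 5 lower, or 28 and 12 adjusted over the list alone (median 0.26, adjusted p = 0.00013, 0.18 with an estimated correlation). MDM2 rose from 146 ± 7.08 to 930.1 ± 44.5 CPM (edgeR log2 fold change 2.68 ± 0.10, adjusted p = 0.00017) and CDKN1A from 71.7 ± 13.9 to 428 ± 67 CPM (log2 fold change 2.58 ± 0.18, adjusted p = 0.00062). BAX rose by 1.61 ± 0.11, CCNG1 by 1.71 ± 0.09 and RPS27L by 1.66 ± 0.10 on the log2 scale. Of 31 apoptosis genes 1 rose and 1 fell, with BCL2L1 higher (2.13 ± 0.11), and the list did not pass (median -0.03, adjusted p = 0.44). For ATM the log2 fold change was -0.16 ± 0.08 (adjusted p = 0.34).

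Marker lists of other lymphocytes were lower at 24 h. Of 13 NK and cytotoxic markers 7 fell (median -0.94, camera adjusted p = 2.8e-05, 0.2 with an estimated correlation), with granzyme A (GZMA) from 91.1 ± 17.3 to 27.2 ± 5.54 CPM (log2 fold change -1.74 ± 0.20, adjusted p = 0.004), CTSW at -1.25 ± 0.13 and CD160 at -1.43 ± 0.17. Of 21 T cell markers 5 fell and 0 rose, or 10 and 1 adjusted over the list alone (median -0.41, adjusted p = 4e-05, 0.25 with an estimated correlation), among them CD27 (-0.98 ± 0.12) and the T cell receptor component CD3E (-0.76 ± 0.11). In the lymphocyte activation list, which did not pass (median 0.30, adjusted p = 0.44), IFNG, the gene of interferon gamma, rose by 2.44 ± 0.42 and the transcription factor TBX21 fell by 1.12 ± 0.19. IFNG lost its call without untreated replicate 1 or irradiated replicate 2 (adjusted p 0.061 to 0.07). TBX21 lost its call without untreated replicate 1 or 3 or irradiated replicate 2 (adjusted p 0.054 to 0.074).

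Myeloid and platelet markers were higher at 24 h. Platelet markers were all positive, with 4 of 12 called (median 0.86, adjusted p = 2.7e-07, 0.077 with an estimated correlation), including the integrin ITGA2B (0.96 ± 0.17) and TUBB1 (0.94 ± 0.15). For monocyte and macrophage markers, 3 of 17 rose and 1 fell (median 0.39, adjusted p = 0.035, 0.33 with an estimated correlation), with ITGAX at 1.45 ± 0.13 and APOE at -0.69 ± 0.12. Neutrophil markers (median 0.68, adjusted p = 0.015, 0.29 with an estimated correlation) had 2 of 16 called, both higher, including AQP9 (1.41 ± 0.23). Adjusted over the list alone 6 were higher and 1 lower, as in DESeq2. Erythroid markers (median 0.86, adjusted p = 0.047, 0.46 with an estimated correlation) had 1 called, and lost the list's call with RLE scaling (adjusted p = 0.06) and with the stricter filter (0.13). Stromal and endothelial markers did not pass (median 0.49, adjusted p = 0.62), while CDH5, the adhesion protein of endothelial junctions, fell by 2.16 ± 0.23. Without untreated replicate 1 the monocyte, neutrophil and erythroid lists had adjusted p of 0.17, 0.059 and 0.19. Other single libraries whose omission ended a call were untreated replicate 2 (neutrophil 0.061, erythroid 0.064), untreated replicate 3 (monocyte 0.062), irradiated replicate 1 (monocyte 0.14, erythroid 0.1) and irradiated replicate 3 (erythroid 0.16, median 0.47). Without irradiated replicate 2 the neutrophil median was 0.37 (adjusted p = 0.026). ITGA2B lost its call without untreated replicate 1 or 2 or irradiated replicate 3 (adjusted p 0.053 to 0.061). TUBB1 lost its call without irradiated replicate 2 (adjusted p = 0.062). APOE lost its call without untreated replicate 2 or 3 or irradiated replicate 2 (adjusted p 0.067 to 0.1). AQP9 lost its call without untreated replicate 3 or irradiated replicate 2 (adjusted p 0.054 to 0.073). With all 12 libraries in 1 fit ITGA2B had an adjusted p of 0.054.

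Ribosomal protein genes were lower at 24 h as a list. Of 40 tested 14 fell and 1 rose, or 25 and 1 adjusted over the list alone, and 39 had a negative log2 fold change (median -0.34, camera adjusted p = 7.9e-12, 0.14 with an estimated correlation). With the replicate block, by the numbers as labelled, 3 were called lower and 1 higher, and the list passed (camera adjusted p = 4.3e-10). RPLP1 fell by 0.79 ± 0.12 and RPS4X by 0.57 ± 0.09 on the log2 scale. RPS19 alone rose, from 762 ± 36.9 to 1423 ± 118 CPM (edgeR log2 fold change 0.90 ± 0.10, adjusted p = 0.0045). Ribosomal protein genes have many processed copies, so the split of reads among them is uncertain. B cell, NK and T cell markers were lower as lists in the same libraries. DNA replication (median -0.22, adjusted p = 0.00075, 0.2 with an estimated correlation) and DNA repair genes (median -0.16, adjusted p = 0.0013, 0.25 with an estimated correlation) were lower as lists. The S phase transcription factor E2F1 fell by 1.98 ± 0.27 and the helicase subunit MCM3 by 0.82 ± 0.09, while DNA2 rose by 1.49 ± 0.12. Mitosis genes were lower (median -0.20, adjusted p = 0.016, 0.45 with an estimated correlation), a call lost without untreated replicate 1 (median -0.11, adjusted p = 0.1), after thinning to the lowest library total (-0.13, 0.08) and with the stricter filter (-0.15, 0.068). RPLP1 lost its call without untreated replicate 1 or 3 or irradiated replicate 2 (adjusted p 0.052 to 0.07). RPS4X lost its call without untreated replicate 1 or 3 or irradiated replicate 2 (adjusted p 0.062 to 0.079). RPS4X had an adjusted p of 0.052 with the replicate block, which at 24 h may rest on wrong pairs.

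NF-kB and inflammatory genes were higher at 24 h (median 0.43, adjusted p = 4.5e-06, 0.2 with an estimated correlation), with 4 of 34 called higher and 1 lower. IL6 rose by 1.99 ± 0.32, the IL-23 subunit IL23A by 0.79 ± 0.10 and the prostaglandin synthase PTGS2 by 0.66 ± 0.10, while the adhesion protein VCAM1 fell by 0.98 ± 0.17. Immediate early genes (median 0.59, adjusted p = 2.8e-05, 0.46 with an estimated correlation), NRF2 genes (median 0.43, adjusted p = 0.0017, 0.33 with an estimated correlation) and glycolysis and hypoxia genes (median 0.31, adjusted p = 0.00013, 0.25 with an estimated correlation) were also higher as lists, with 1, 0 and 2 members called. Platelet, neutrophil and monocyte markers were higher as lists in the same libraries (medians 0.86, 0.68 and 0.39). Without irradiated replicate 3 the immediate early median was 0.20 (adjusted p = 0.007), and without irradiated replicate 1 the NRF2 median was 0.27 (0.021). For NRF2 genes edgeR gave 3 higher at an unadjusted p below 0.05 and DESeq2 called 0. PFKFB3, which makes the activator of glycolytic phosphofructokinase, rose by 0.65 ± 0.12. Interferon-stimulated genes (median -0.17, adjusted p = 0.1) and the unfolded protein response (median 0.10, adjusted p = 0.27) did not pass. The serine and asparagine synthesis genes PHGDH and ASNS of the latter list fell by 0.95 ± 0.17 and 0.85 ± 0.16. Interferon genes were lower without untreated replicate 1 (0.0047), untreated replicate 3 (0.014) or irradiated replicate 1 (0.00092). IL6 lost its call without irradiated replicate 2 (adjusted p = 0.065). PTGS2 lost its call without untreated replicate 1 or irradiated replicate 2 or 3 (adjusted p 0.052 to 0.061). VCAM1 lost its call without untreated replicate 1 or 3 or irradiated replicate 2 (adjusted p 0.053 to 0.074). PFKFB3 lost its call without untreated replicate 1 or 3 or irradiated replicate 2 or 3 (adjusted p 0.077 to 0.1). PHGDH lost its call without untreated replicate 1 or irradiated replicate 2 or 3 (adjusted p 0.056 to 0.097). ASNS lost its call without untreated replicate 1, 2 or 3 or irradiated replicate 2 or 3 (adjusted p 0.052 to 0.11). With all 12 libraries in 1 fit PTGS2 had an adjusted p of 0.13.

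**Figure D2:**
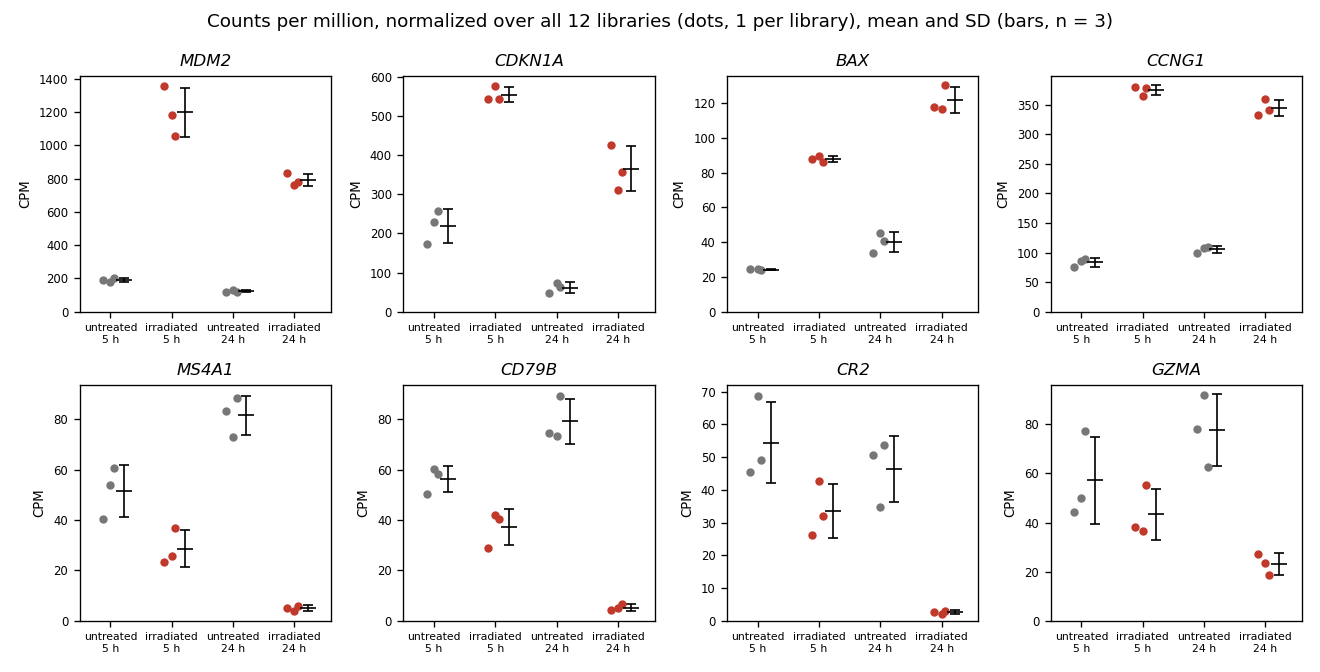
CPM (y axis, scaled over all 12 libraries together, so levels differ from those quoted per time point) of 4 p53 targets (upper row) and 4 lymphocyte genes (lower row) in each library, with the mean and SD of n = 3. MS4A1 lies between 73.1 and 88.3 CPM in untreated and between 3.79 and 5.98 CPM in irradiated libraries at 24 h.

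The calls of both times overlapped. Among 12814 genes tested at both, 143 were higher at 5 h and 254 at 24 h, and 77 were shared against 2.83 for independent lists (Fisher's exact test over genes, two-sided p = 4.7e-96). MDM2, CDKN1A, PHLDA3, GNAT1 and TNS1 were among them. Of 62 and 705 lower genes, 40 were shared against 3.41 (Fisher's exact test, p = 1.6e-35), FAM129C and FCRL1 among them. With the replicate block in both fits 151 higher and 292 lower genes were shared, against 23.9 and 48.1. The block at 24 h uses the numbers as labelled and may rest on wrong pairs.

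**Figure D3:**
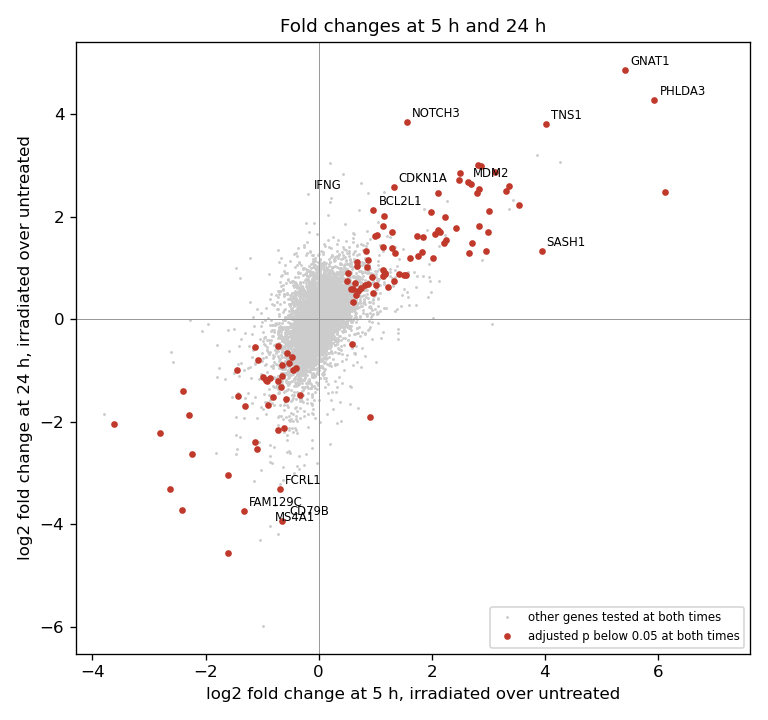
Log2 fold change at 5 h (x axis) against that at 24 h (y axis), irradiated over untreated, for genes tested at both times, red where the adjusted p is below 0.05 at both. MDM2 lies at 2.64 and 2.68, and FAM129C at -1.32 and -3.74.

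The interaction tested which irradiation effects differed between the times. It called 134 of 15200 genes, 115 more negative and 19 more positive at 24 h. The largest negative differences were of CR2 (-3.47 ± 0.34 on the log2 scale, edgeR adjusted p = 0.00032), CD79B (-3.31 ± 0.24), PLD4 (-3.30 ± 0.28), CLEC9A (-3.26 ± 0.65) and MS4A1 (-3.18 ± 0.29). The largest positive ones were of SULF2 (2.87 ± 0.52, adjusted p = 0.022), IFNG (2.62 ± 0.52), SLC16A10 (1.82 ± 0.34), the endopeptidase PHEX (1.68 ± 0.27) and AQP9 (1.67 ± 0.28). Of 17 B cell markers 12 were more negative at 24 h (camera adjusted p = 5.3e-25, 0.025 with an estimated correlation), the only list of 21 that held so. The count was 82, 87, 76, 85, 81 and 86 without 5 h untreated replicate 1 or 3, 5 h irradiated replicate 2 or 3, and 24 h untreated replicate 1 or 3. CLEC9A had an adjusted p of 0.062 with the replicate block, which uses the numbers as labelled. CLEC9A lost its call without 5 h untreated replicate 1, 2 or 3, 5 h irradiated replicate 2 or 3, 24 h untreated replicate 1 or 2 or 24 h irradiated replicate 2 or 3 (adjusted p 0.055 to 0.12). SULF2 lost its call without 5 h untreated replicate 1 or 3, 5 h irradiated replicate 2 or 3, 24 h untreated replicate 3 or 24 h irradiated replicate 2 (adjusted p 0.052 to 0.068). IFNG lost its call without 5 h untreated replicate 1, 2 or 3, 5 h irradiated replicate 1, 2 or 3, 24 h untreated replicate 1 or 24 h irradiated replicate 2 or 3 (adjusted p 0.058 to 0.11). SLC16A10 lost its call without 5 h untreated replicate 2 or 3, 5 h irradiated replicate 1, 2 or 3, 24 h untreated replicate 1 or 3 or 24 h irradiated replicate 2 or 3 (adjusted p 0.051 to 0.083). Of 21 lists 14 were called, and the medians of the others were -0.00077 for p53 targets (adjusted p = 0.22), 0.04 for apoptosis (adjusted p = 0.41), -0.05 for interferon-stimulated genes (adjusted p = 0.81), 0.09 for the unfolded protein response (adjusted p = 0.27), 0.22 for lymphocyte activation (adjusted p = 0.28), -0.20 for T cell markers (adjusted p = 0.09) and 0.24 for stromal markers (adjusted p = 0.77). T cell markers passed with the replicate block by the numbers as labelled (camera adjusted p = 0.021, 0.47 with an estimated correlation as well).

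Untreated cells changed more between 5 h and 24 h than irradiation changed them at either time in these counts. Of 13445 genes 8490 passed, 4383 higher and 4107 lower at 24 h, relative to a median of 0.11 over all genes. Which direction had more calls depended on the processing, with 4069 higher and 4345 lower under RLE scaling, 3567 and 4361 in DESeq2, 3823 and 4269 without a filter and 3043 and 3349 at an adjusted p below 0.01. More were higher with a 2-fold minimum (2007 and 1353), the stricter filter (4342 and 3886), the replicate block (4149 and 3952) and all 12 libraries in 1 fit (4549 and 4301). Leaving out untreated replicate 1, 2 or 3 of 5 h gave 3429 and 3790, 3535 and 3810, 3692 and 4022, and of 24 h 3669 and 3837, 4054 and 4333, 4084 and 4201. The largest rises were of the lipid antigen-presenting proteins CD1C (from 0.41 ± 0.19 to 81.1 ± 27.8 CPM, edgeR log2 fold change 7.63 ± 0.37, adjusted p = 2.2e-06) and CD1E (7.24 ± 0.22), the complement protease C1R (7.38 ± 0.42), ENOX1 (7.31 ± 0.31) and CHGB (7.25 ± 0.31). The largest falls were of the protease inhibitor SERPINB2 (from 1574 ± 672 to 11.5 ± 2.92 CPM, log2 fold change -7.10 ± 0.40, adjusted p = 3.5e-06), C1QL2 (-7.10 ± 0.27), CALCA (-6.39 ± 0.36), the vasoconstrictor peptide gene EDN1 (-6.21 ± 0.53) and COL15A1 (-6.12 ± 0.32). The NF-kB and inflammatory list was lower at 24 h (median -1.03, 25 of 34 lower, adjusted p = 3.8e-05), as were neutrophil markers (median -1.74, 10 of 15 lower, 0.0033) and ribosomal proteins (median -0.29, 0.0082). DNA replication genes (median 0.43, 0.019) and NK and cytotoxic markers (median 0.57, 0.044, but 0.054 with the replicate block) were higher. Each of these 5 lists had an adjusted p of 0.91 with an estimated correlation. The others did not pass, with medians of 0.33 for p53 targets (adjusted p = 0.29), 0.15 for DNA repair (adjusted p = 0.44), 0.20 for mitosis (adjusted p = 0.22), 0.36 for apoptosis (adjusted p = 0.46), -0.25 for interferon-stimulated genes (adjusted p = 0.22), -0.10 for immediate early genes (adjusted p = 0.46), -0.45 for NRF2 genes (adjusted p = 0.22), -0.20 for the unfolded protein response (adjusted p = 0.23), 0.22 for glycolysis (adjusted p = 0.46), 0.09 for lymphocyte activation (adjusted p = 0.91), 0.41 for T cell markers (adjusted p = 0.21), 0.36 for B cell markers (adjusted p = 0.22), -0.12 for monocyte markers (adjusted p = 0.91), -0.45 for platelet markers (adjusted p = 0.46), -0.13 for erythroid markers (adjusted p = 0.7) and 0.48 for stromal markers (adjusted p = 0.46). Time after the start and any batch difference between the time points cannot be separated here.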

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

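The tests of library depth, of single libraries and of dilution for the B cell markers were chosen after their result was seen.

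The irradiation effect differed between 24 h and 5 h for the genes and lists below, by the edgeR interaction test over 12 libraries or camera on that interaction. More negative at 24 h were B cell genes and others, by -3.47 for CR2, -3.31 for CD79B, -3.30 for PLD4, -3.26 for CLEC9A, -3.18 for MS4A1, -2.63 for FCRL1, -2.43 for FAM129C, -1.49 for CD22 and -1.76 for CDH5 on the log2 scale. SASH1 rose by 3.94 at 5 h and less at 24 h (difference -2.61 (adjusted p = 0.02)), and BARD1 differed by -0.68 (adjusted p = 0.045). More positive at 24 h were IL23A (0.85), BCL2L1 (1.16), CDKN1A (1.24), AQP9 (1.67), PHEX (1.68), SLC16A10 (1.82), IFNG (2.62) and SULF2 (2.87). Among lists, the median difference was -2.33 (adjusted p = 5.3e-25) for B cell markers, -0.68 (adjusted p = 7.5e-05) for NK and cytotoxic markers, -0.35 (adjusted p = 2.9e-14) for ribosomal proteins, -0.13 (adjusted p = 0.027) for DNA replication and -0.11 (adjusted p = 0.0016) for DNA repair. It was 0.19 (adjusted p = 0.0032) for mitosis, 0.38 (adjusted p = 1.1e-06) for NF-kB genes, 0.40 (adjusted p = 0.00075) for immediate early genes, 0.47 (adjusted p = 1.8e-05) for NRF2 genes and 0.34 (adjusted p = 1.8e-05) for glycolysis. For markers of monocytes it was 0.19 (adjusted p = 0.039), of neutrophils 0.50 (adjusted p = 0.00093), of platelets 0.69 (adjusted p = 7e-06) and of erythroid cells 0.89 (adjusted p = 0.047). With an estimated correlation the B cell list alone held (adjusted p = 0.025).

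The B cell marker list was lower at 24 h, but not with an estimated correlation (adjusted p = 0.071, 0.4 with the replicate block as well), while 14 of its 16 tested genes fell. The block at 24 h uses the numbers as labelled and may rest on wrong pairs. It also leaves few residual degrees of freedom when the correlation is estimated, so its value is uncertain. The median was -2.78 after thinning all 6 libraries to the lowest total. Thinning keeps the expected share of each gene in its library, so it could hardly move this median and cannot decide on depth. No single library carried the lower values, as the median reached at most -2.49 when 1 was left out. The list has 20 genes, of which 16 were tested at 24 h, and none is in another list. Its most abundant member in untreated libraries, FCER2 (559 CPM), was not called (log2 fold change -0.86, adjusted p = 0.5), CD22 (172 CPM) fell by 1.89 and CD72 (96.4 CPM) was not called (0.20, 0.32). Dilution of all lymphocyte RNA alike is argued against by the B cell median lying -2.39 from the T cell median. A candidate explanation is a response of B cells to irradiation, which stays a hypothesis, and whether B cells were lost or lowered these transcripts was not tested.

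The ribosomal protein list was lower at 24 h, with a median of -0.34, 14 of 40 genes called lower and 1 higher, but not with an estimated correlation (adjusted p = 0.14). The replicate block, by the numbers as labelled, called 3 lower and 1 higher. Shorter genes tended to lower log2 fold changes at 24 h (Spearman correlation with length 0.13). Of 10000 random lists matched on bins of length and mean expression, 0% had a median as low, and the lowest was -0.21. That argues against a bias shared by genes of the same bins. A bias within a bin is not covered, and genes drawn singly do not carry the correlation within a list. Scaling is not excluded. With RLE size factors the median was -0.32, but they moved the median of all genes by only 0.02, too little to test a fall of this size. The rule written before this test would have excluded the scaling, and it was changed after the value was seen for that reason. A lower share of lymphocytes stays open, because their marker lists were lower in the same libraries, and irradiation itself stays an untested explanation.

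The replicate block raised the count at 5 h from 207 to 2655. In counts simulated for 5 h without a replicate effect the block gave 200 calls, against 198 without the block, so there it hardly changed the count. With a replicate effect simulated the counts were 217 and 169. The simulated spread was that of the fit without the block, which already holds the differences between the real pairs. So these simulations cannot show what the block does to the real count. Whether the block raises calls for any grouping of the real libraries is left open. The other 3 splits that part the pairs called at most 0, but each exchanges 1 pair and so puts the irradiation effect into the residual, and without the block they called none either, so this count excludes nothing. The rule written before this test would have excluded the block as the cause, and it was changed after the count was seen, because the splits cannot test it. Differences between the pairs that both groups share are a candidate explanation, and what the pairs are is not given in the sources used here.

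For the counts of changed genes, the 6 libraries of a comparison make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 207 calls at 5 h, 968 at 24 h and 8490 over time in untreated cells, and it was 1 of 10 with as many in each, with 0 in the highest other split. Each other split mixes the compared groups on both sides, which puts their real difference into the residual. The 0 calls there are therefore no support for the real counts. For the interaction, chance cannot be excluded by this count, as 9 of 100 splits drawn within the times, the real one included, called as many as its 134 genes and the highest other called 1521. All 8 others kept the untreated and irradiated libraries of at least 1 time wholly apart, so they contain irradiation effects, a structure of the samples. The highest kept those of both times apart with the groups exchanged at 24 h, so it adds the effects of both.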

How the results depend on the processing

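DESeq2 with the replicate block, the block with an estimated correlation and thinning were chosen after seeing the data. Where no cause is given, the cause was not tested. DESeq2 called 417 genes at 5 h (54.4% higher, against 70.0%), 1545 at 24 h and 341 for the interaction. The replicate block gave 2655 at 5 h (51.6% higher) and 443 shared between the times against 117, and DESeq2 with the block gave 1420 at 5 h. An adjusted p below 0.01 left 88 at 5 h, 261 at 24 h, 55 for the interaction and 46 shared, and a 2-fold minimum 117, 373, 3360 over time in untreated cells and 61 shared, both by construction. All 12 libraries in 1 fit gave 1670 at 24 h, yet ended calls of SULF1 (0.33), MCOLN3 (0.054), KIF18B (0.077), GADD45G (0.66), S100A9 (0.44) and TNFSF4 (0.11) at 5 h and of PTGS2 (0.13), IL7R (0.053), ITGA2B (0.054) and VWF (0.12) at 24 h. Leaving out 1 library gave 86 to 191 calls at 5 h, 293 to 1061 at 24 h, 76 to 168 for the interaction and 7219 to 8387 for untreated cells over time. The number of lists called at 5 h was 6, with 1 under an estimated correlation, 0 with the replicate block as well, and 3 to 9 on leaving out 1 library (3 without irradiated replicate 1). At 24 h it was 16, with 0 under an estimated correlation and 0 with the block as well. Few residual degrees of freedom limit what can pass under an estimated correlation, most of all with the block. fry gave 9 lists at 5 h and 17 at 24 h for change in either direction. For change in a shared direction it gave 1 at 5 h, p53 targets (adjusted p = 8.8e-05), and 10 at 24 h. The mitosis, replication, B cell, T cell and immediate early lists of 5 h did not pass it (0.25, 0.37, 0.28, 0.64 and 0.64). At 24 h B cell markers passed it (0.0001), while mitosis (0.12), immediate early (0.24), NRF2 (0.12), monocyte (0.11), neutrophil (0.11) and erythroid lists (0.31) did not. RLE scaling and both filters kept the gene counts of the 4 comparisons within 1.5 times, RLE scaling and the stricter filter kept those of lists so, and thinning kept both at 24 h. The shared count was not repeated under these.

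At 24 h the numbers do not pair the libraries, with same-number correlations of -0.15, -0.58 and 0.85. Replicate 3 correlated best with its own number, while untreated 2 went with irradiated 1 at 0.83 and untreated 1 with irradiated 2 at 0.53. So the libraries may be paired with numbers 1 and 2 exchanged in 1 group, which was not fitted, and block values that use the 24 h numbers may rest on wrong pairs. By the numbers as labelled the replicate block gave 707 calls at 24 h, 139 for the interaction and 8101 over time in untreated cells. DESeq2 alone also called CD22 (0.017), CD27 (0.012) and BRCA1 (0.035) at 5 h. There the block made 12 of 49 named genes pass that had not, and ended 0 calls among them.

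A list's direction here is the sign of its median, a choice made after the first results were seen. Camera's direction was the opposite for ribosomal proteins at 5 h. In untreated cells over time it was so for lymphocyte activation and erythroid markers. Among lists and named genes at 5 h and 24 h, direction changed only in results that did not pass. On leaving out 1 library the 5 h medians ranged from -0.252 to 0.0514 for stromal, -0.0531 to 0.0051 for DNA repair, -0.22 to 0.451 for platelet, -0.342 to 0.279 for erythroid, -0.254 to 0.0702 for interferon, -0.135 to 0.0225 for NF-kB, -0.0622 to 0.0254 for NRF2, -0.0854 to 0.0504 for ribosomal protein, -0.222 to 0.0483 for lymphocyte activation, -0.0349 to 0.247 for neutrophil and -0.0128 to 0.0426 for unfolded protein response genes. At 24 h they were -0.117 to 0.0226 for apoptosis (0.0028 with the stricter filter) and -0.336 to 0.0716 for interferon genes. Over named genes with a call, leaving out 1 library in turn (6 refits per gene) lost it in 31.9% of refits at 5 h and 24.7% at 24 h. All refits without a library were made without the block, so at 5 h they do not use the pairs. They also have fewer libraries, so a lost call does not show that 1 library carried it.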

Other observations

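The test of neighbouring genes was chosen after the genes that rose at 5 h were seen, so the pattern is a hypothesis. Of 145 genes that rose, 8 pairs were neighbours among tested genes, within 20000 bp on a scaffold. In 10000 random placements among tested genes the mean was 0.63 and the highest 5 (permutation test, one-sided p = 0.0001, the smallest these placements can give). The stress transcription factor ATF3 rose by 2.03 and its neighbour FAM71A by 1.82 on the log2 scale, on scaffold 148 with a gap of 5606 bp and on the same strand. The adhesion protein gene PVRL4 rose by 2.97 and KLHDC9 by 1.96, PHYHD1 by 1.85 and the volume-regulated channel subunit LRRC8A by 1.33, and PIBF1 by 0.67 and the exosome nuclease DIS3 by 1.55. LACTB rose by 0.34 beside RPS27L. These pairs were named after their values were seen. Of the 8 pairs, 5 are on the same strand, against 47.1% of all neighbouring pairs tested. Chance placement is not excluded, because the test was chosen after these genes were seen and was run on the same genes. Transcription running from a gene into the next, shared promoters, gene models that split 1 gene, and reads counted without strand may each give such pairs, and they were not told apart here.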
